A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

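Single-stranded DNA (ssDNA) was mapped across the Saccharomyces cerevisiae genome on 8 Agilent 2-colour oligonucleotide arrays. Per the labels' protocols, cells grown at 30 °C were arrested in G1 with 3 µM α factor, moved to 37 °C for the last 15 min of the arrest, and released with 0.3 mg/ml pronase. Samples were taken at 10, 15, 20 and 25 min. ssDNA in agarose-embedded chromosomes was labelled by random-primed synthesis with Klenow (exo-), an enzyme that copies single-stranded template, and the DNA was sheared to about 500 bp. On every array Cy3 held the S-phase DNA and Cy5 the G1 DNA of the same strain, per the labels, with no dye swap. A ratio above the array's median therefore means more S-phase signal relative to G1 than at the typical probe of that array. A change shared by all probes is not seen, and without a dye swap an effect of the dye on a probe cannot be told apart. Time points are given as minutes after release, as the protocol states them. The sample labels word the same numbers as minutes after the shift to 37 °C.

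The labels name BY4741, a laboratory strain, as wild type (WT) and BY4741 hpr1Δ as the mutant. Each of the 8 combinations of strain label and time had 1 array, and the 4 arrays of each strain label shared a slide. No replicate test was possible, and slide and strain label cannot be told apart. No p-value was computed. A mean over the 4 time points is given with the SD over them (n = 4 time points), and these time points are not replicates.

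Agilent Feature Extraction 9.5.1 made the values, per the submitters' processing notes. The deposited scanner output holds intensity values for both channels, which the software had background-subtracted, spatially detrended and scaled by a linear dye-normalization factor per channel, per the file headers. Spots not above background carry surrogate values. The deposited log10 ratio (red over green) was checked only: it departed by more than 0.01 from the ratio of processed signals for 5.29% of values. A deposited table of the whole series holds, from the authors, a linear ratio of Cy3 over Cy5 per nuclear probe. It equalled the ratio of the processed signals of the same scanner file to within rounding, with no centring. Its median ratios lay between 0.896 on the WT 25 min array and 1.07 on the hpr1Δ 20 min array.

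From the processed signals, log2(Cy3/Cy5), called log2(S/G1) here, was computed for 41480 nuclear probes. The 295 mitochondrial probes were kept apart. Spots with an outlier flag in either channel were removed and each array was centred on its median. The median spacing of probes was 256.5 bp.

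The genome build of the array is not given in the sources used here, and coordinates are those of the array. Positions of genes came from the offsets in the probe annotation, and names and lengths from a RefSeq gene table of assembly R64, which matched 5674 of 5698 annotated genes. Array positions differed from that table by a median of 0.5 to 359.5 bp depending on the chromosome. Each centromere was placed at the middle of the gap between the innermost genes of the left and right arms. tRNA genes (228 of 275) and snoRNA genes (68 of 76) were placed in the middle of the gap between their neighbouring coding genes where that gap was at most 4 kb. Origin annotation and the positions of Ty elements and LTRs were not used here, so the planned early, late and dormant origin lists and the Ty list were not analysed. In place of annotated origins, 463 ssDNA peak regions were used: local maxima of at least 0.5 of the mean of all 8 arrays, smoothed over 1 kb on each side and at least 5 kb apart. These regions were selected on the same arrays that they describe.

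Windows held the probes within 1 kb of a site (at least 3 probes). The summary of a set was the median over its members, on each array or for the difference labelled hpr1Δ minus labelled WT. It was set against 10000 random sets of as many windows, genes or segments, and its percentile among them describes these arrays. For differences the random sets were matched on the decile of the mean log2(S/G1) over 8 arrays. A set is said to stand apart when its percentile was below 2.5 or above 97.5. The pericentromere was the region 3 to 10 kb from a centromere, chromosome ends were the outer 30 kb, and long coding regions were over 3 kb. Bins were 1 kb wide with at least 2 probes (11075 bins). On simulated arrays with the noise of the real ones, 8% of 100 sets of 16 windows with no planted difference stood apart in the mean over time points, as did 98% with 0.2 added to the hpr1Δ-labelled arrays. For the bin rule, 39.5% of 200 bins with 0.5 added and 90.5% with 1 added were called, with 131 false calls in each case.

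Genes and regions to name were fixed before the data were examined: the 16 centromeres; HPR1 and the BY4741 marker genes MET15, LEU2, URA3 and HIS3; the 10 bins with the largest difference in each direction among those with the same sign at all 4 times, bins within 2 kb counting as 1; the 5 highest peak regions of each strain label; and the 2 highest and 2 lowest members of each list. In this rule peak regions took the place of annotated origins after the data were seen. RGP1 and the local centromere comparison (windows minus the region 3 to 10 kb away) were added then too. The marker genes and HPR1 were read in each channel alone, as the median log2 processed signal of the probes inside the gene minus the array's median. Runs of at least 3 adjacent probes at least 8-fold below the median in both channels on all 4 arrays of a label were listed as lost.

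Alternatives were normexp background correction (offset 50), loess within each array, scaling to a common robust SD, the deposited table, probes well above background everywhere (24531 probes), flagged spots kept, windows of 0.5, 2.5 and 5 kb, means over sites, unmatched random sets, bin thresholds of 0.3 and 1, 5-kb bins, centring per chromosome, and leaving out each time point or centromere. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.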

Results

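ssDNA formed during S phase at 37 °C was profiled in cells labelled wild type and cells labelled hpr1Δ, which should lack a subunit of the THO complex that couples transcription to mRNA export. The series concerns R loops (RNA-DNA hybrids with a displaced single strand) at centromeres, so the main question was whether S-phase ssDNA near centromeres differed between the strain labels. There were 8 arrays in 8 groups of 1: 2 strain labels at 10, 15, 20 and 25 min after release from G1. No value has a replicate, and the number of arrays limits the precision.

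The targeted gene was read first. HPR1 (YDR138W, chromosome 4, 730571 to 732829) gave signal on every array labelled hpr1Δ. Its 7 inside probes had a mean G1 (Cy5) signal of -0.11 ± 0.14 log2 units from the array median (SD over 4 arrays) and an S-phase (Cy3) signal of -0.18 ± 0.37. On the arrays labelled WT the values were 0.86 ± 0.15 and 0.11 ± 0.13. The neighbouring gene RGP1 (YDR137W, chromosome 4, 728252 to 730243), which encodes a subunit of a Golgi exchange factor, was instead lost on the arrays labelled hpr1Δ. Its 8 inside probes lay at -5.86 ± 0.36 in Cy5 and -6.35 ± 0.54 in Cy3 there, against 0.73 ± 0.36 and 0.09 ± 0.16 on the arrays labelled WT. RGP1 was singled out after its values were seen. The measured DNA thus went against the hpr1Δ label, and every strain difference below is a difference between labels.

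**Figure D1:**
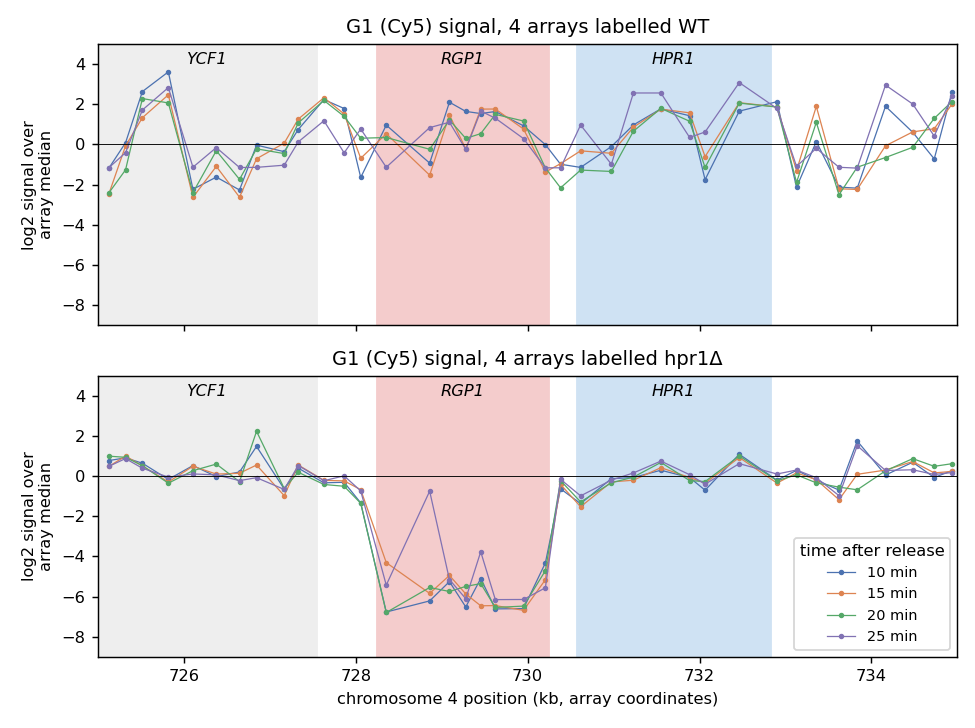
G1 (Cy5) log2 signal relative to the array median (y axis) along chromosome 4 (x axis, kb) for the 4 arrays of each strain label, 1 point per probe and 1 line per time point, with coding regions shaded. On the arrays labelled hpr1Δ the RGP1 probes had a mean of -5.86 and the HPR1 probes -0.11.

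The BY4741 markers differed between the labels too. MET15, LEU2 and URA3, genes of methionine, leucine and uracil synthesis that BY4741 lacks, were lost on the arrays labelled hpr1Δ, with mean Cy5 signals of -5.87 ± 0.47, -4.97 ± 0.59 and -5.54 ± 0.64. These are medians over probes, and for MET15 the loss covered 2 of 3 probes: the other had a Cy3 signal of 0.98, 0.48, -1.62 and -2.03 at 10, 15, 20 and 25 min. HIS3, which BY4741 lacks in part, had 1 probe with signal (Cy3 of 0.56 to 0.82) and 1 without (-7.38 to -5.01). On the arrays labelled WT all of them gave signal in Cy3. Mean Cy3 values were -0.36 ± 0.29 for MET15, -0.46 ± 0.79 for LEU2, -0.69 ± 0.34 for URA3 and 0.33 ± 0.14 for HIS3. In the same order the mean Cy5 values were -0.66 ± 0.87, -0.86 ± 0.70, -0.88 ± 0.93 and 0.46 ± 0.25. Runs of lost probes numbered 6 on the arrays labelled hpr1Δ and 0 on those labelled WT. The 6 were in LEU2, RGP1, URA3, MET15 and at 2 places between SRD1 and MAK32 on chromosome 3 (149630 to 150208 and 150727 to 151480). The 2 chromosome 3 runs were also low in Cy3 on the arrays labelled WT, at -4.70 ± 0.33. In Cy5 these runs lay at -1.98 ± 0.65 there, with single arrays from -2.66 to -1.14. The rule for a lost run needs -3 or lower in both channels, so it passed over them on the dim slide. The count of 0 therefore cannot decide whether sequence was lost under the WT label.

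The slide labelled WT was much dimmer. Median background-subtracted signal was 72.7 to 129 in Cy3 and 3.61 to 16.6 in Cy5, against 789 to 1571 and 140 to 388 on the slide labelled hpr1Δ. Cy5 was well above background for 68.5% of nuclear probes on the WT 25 min array and for at most 88.5% on the other arrays of that label. It was so for at least 99.98% on every array labelled hpr1Δ. The probe-to-probe noise of log2(S/G1) was 0.67 to 1.17 on the slide labelled WT and 0.24 to 0.40 on the other. All pairs of arrays correlated positively across 1-kb bins, with a lowest r of 0.26. Across the peak regions some pairs correlated negatively, lowest at -0.42 between WT 15 min and hpr1Δ 25 min.

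More 1-kb bins reached a log2(S/G1) of 0.5 at 15 min than at 10 min. Probe noise also lifts bins over 0.5, more so on the noisier slide labelled WT (0.67 to 1.17 against 0.24 to 0.40). Its share of the counts was not computed, so they do not measure a difference between the labels. The number of 1-kb bins at or above 0.5, of 11075, was 1842, 2879, 2370 and 2117 at 10, 15, 20 and 25 min on the arrays labelled WT. On those labelled hpr1Δ it was 899, 2634, 2723 and 1941. The WT time course depended on background correction: with normexp its counts were 2178, 793, 683 and 532, highest at 10 min, and those of the hpr1Δ label were 1199, 2706, 1553 and 2503. Over the 463 ssDNA peak regions the median log2(S/G1) was 0.66, 1.00, 0.78 and 0.71 for the WT label and 0.49, 0.95, 0.92 and 0.59 for the hpr1Δ label. The maximum fell at 15 min for 238 of these regions under the WT label and for 218 under the hpr1Δ label. The hpr1Δ label had its maximum at 20 min in 165 regions and the WT label in 85. At 25 min the order was reversed, with 57 regions under the hpr1Δ label and 123 under the WT label. Noise also decides where a maximum falls, and the WT 25 min array was the noisiest, with a probe noise of 1.17. Its median over the regions (0.71) was below that at 20 min (0.78) although more maxima fell there. These counts therefore do not show a difference in timing.

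The highest peak regions were ranked for each label on that label's own arrays. A difference between the 2 lists is therefore not evidence of a difference between the labels. Under the WT label the highest mean over time points was at MNN2 on chromosome 2 (268071 to 270071), with 1.52 ± 0.43. It was followed by the regions of YNL035C and YNL034W on chromosome 14 (1.47 ± 0.24), LSB5, MXR2 and STE50 on chromosome 3 (1.42 ± 0.29), VHR1 on chromosome 9 (1.41 ± 0.28) and COX20 and HEM1 on chromosome 4 (1.38 ± 0.46). Under the hpr1Δ label it was at SPT8 on chromosome 12 (251143 to 253143), with 1.58 ± 0.47. The next were SPC25 and ISC1 on chromosome 5 (1.56 ± 0.38), YJL043W and MHP1 on chromosome 10 (1.54 ± 0.37), YAT1, YAR035C-A and SWH1 on chromosome 1 (1.53 ± 0.30), and RRT12 and IMG1 on chromosome 3 (1.52 ± 0.29). All 10 had a mean above 0.8 under both labels.

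Centromeres and the regions around them had their highest log2(S/G1) at 15 min under both labels. The median over the 16 centromere windows was 0.30, 0.85, 0.22 and -0.40 at 10, 15, 20 and 25 min under the WT label. The first 2 values stood above random sets of windows, at percentiles of 99.2 and 99.98, and the others did not stand apart. Under the hpr1Δ label the medians were -0.04, 1.099, 0.67 and -0.21, and those at 15 and 20 min stood above random sets, at percentiles of 100 and 99.98. These calls depended on the settings. With normexp the levels at 10 and 25 min under the hpr1Δ label stood below random sets (-0.25 and -0.18, percentiles of 0.58 and 0.31). The WT 20 min level stood apart with loess (0.36), with only probes well above background (0.43), with means over sites (0.28) and with windows of 0.5, 2.5 and 5 kb (0.48, 0.41 and 0.46), and the WT 10 min level did not with normexp (0.12, percentile 61.05). The region 3 to 10 kb away was raised too, at 0.35 and 0.78 at 10 and 15 min under the WT label and at 0.87 at 15 min under the hpr1Δ label, each at a percentile of 100. It was also above random sets at 20 min (0.49 under the WT label and 0.33 under the hpr1Δ label) and at 25 min under the WT label (0.09), and below them at 25 min under the hpr1Δ label (-0.26, percentile 0.58). Relative to that region, centromere windows stood apart only at 20 min under the hpr1Δ label (0.38, percentile 98.9). At 15 min 16 of 16 centromeres were above the array median under the hpr1Δ label and 15 of 16 under the WT label.

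Between the labels, centromeres were lower at 10 min and higher at 15 min on the arrays labelled hpr1Δ. The median difference at 10 min was -0.41 (SD over centromeres 0.25), lower at 16 of 16, at a percentile of 0.17 among matched random sets. At 15 min it was 0.29 (SD 0.37), higher at 11 of 16, at a percentile of 99.8. At 20 and 25 min it was 0.15 (SD 0.44, higher at 14 of 16) and 0.09 (SD 0.51, higher at 10 of 16), at percentiles of 56.8 and 46.4. The mean over the 4 time points was 0.11 at the median centromere, at a percentile of 74.4, and between 0.0066 and 0.23 when a time point was left out. With only probes well above background on all arrays, 11 centromeres could be measured: their difference was -0.50 at 10 min but -0.0018 at 15 min, at a percentile of 48.7. At the same 11 centromeres all probes gave 0.12 at 15 min. With windows of 2.5 kb the 15 min difference did not stand apart (0.16, percentile 97.4). With normexp background correction the 25 min difference was -0.25, at a percentile of 0.01, and the 20 min difference stood apart (0.18, percentile 99.3).

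**Figure D2:**
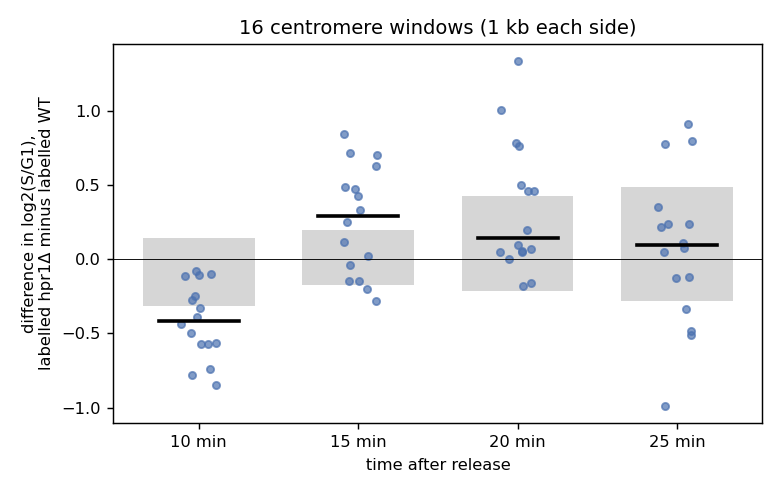
Difference in log2(S/G1), labelled hpr1Δ minus labelled WT (y axis), at each time after release (x axis) for the 16 centromere windows. Points are centromeres, black lines their medians (-0.41, 0.29, 0.15 and 0.09), and grey boxes the central 95% of 10000 matched random sets.

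Single centromeres varied widely. The mean difference over time points was highest at CEN7 (0.47 ± 0.42, n = 4 time points), CEN8 (0.42 ± 0.55), CEN11 (0.26 ± 0.59) and CEN1 (0.21 ± 0.43). It was lowest at CEN5 (-0.42 ± 0.54), CEN10 (-0.32 ± 0.16) and CEN9 (-0.16 ± 0.55). The other means were 0.20 at CEN15, 0.15 at CEN2, 0.13 at CEN6 and CEN13, 0.09 at CEN4, 0.07 at CEN12, 0.06 at CEN3, -0.10 at CEN16 and -0.14 at CEN14. CEN10 alone kept its sign at all 4 time points. Only at CEN10 and CEN7 was the mean larger in size than its SD over the time points.

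The pericentromere followed the centromere at 10 min and had the opposite sign at 20 and 25 min. The region 3 to 10 kb away had median differences of -0.32, 0.09, -0.18 and -0.24, lower at 16 of 16 sites at 10 min and below matched random sets at 10, 20 and 25 min (percentiles of 0.23, 0.09 and 0.10). Its mean over time points was -0.12, at a percentile of 1.93; it was -0.059, at a percentile of 3.09, without the 10 min arrays and 0.085, at a percentile of 47.8, with normexp background correction. With the surrounding region subtracted, a comparison added after the data were seen, the centromere windows differed by -0.06, 0.18, 0.35 and 0.26, and the values at 10 and 15 min did not stand apart, at percentiles of 34.3 and 97.0. The 20 min value stood apart, at a percentile of 99.4, with 14 of 16 centromeres higher, as did the mean over time points of 0.25, at a percentile of 99.5. With only probes well above background these were 0.19, at a percentile of 90.7, and -0.019, at a percentile of 47.2, so neither stood apart there. The mean was also lost as a call without 20 min (0.091) or 15 min (0.18), without CEN2, CEN7 or CEN11 (0.20 each), with normexp (0.019, percentile 90.2) and with robust SD scaling (0.17, percentile 95.2).

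**Figure D3:**
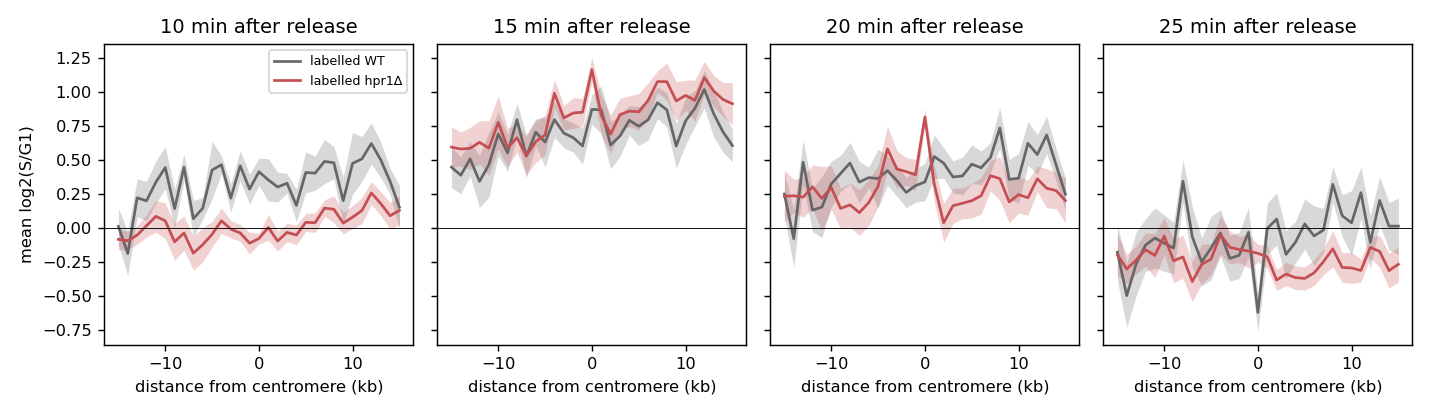
Mean log2(S/G1) of 16 centromeres in 1-kb steps (y axis) against distance from the centromere (x axis, kb), per time point, with shading for the SE over centromeres. Under the hpr1Δ label the mean at 0 kb was 0.82 at 20 min, with 0.39 and 0.32 at 1 kb to the left and right, and 1.17 at 15 min, with 1.11 at 12 kb to the right.

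At the 463 ssDNA peak regions the median differences were -0.14, 0.02, 0.17 and -0.10. Their mean over time points was -0.04, below matched random sets at a percentile of 1.41. This direction was not stable. The mean was positive with normexp (0.36), robust SD scaling (0.24), the deposited table (0.017), only probes well above background (0.030), windows of 2.5 kb (0.027) and without 10 min (0.015). It was -0.23 at peaks called on the arrays labelled WT and 0.26 at those called on the arrays labelled hpr1Δ, each selected on the label it favours. The largest positive mean difference was 0.84 ± 0.13 at YLR161W, YLR162W and RRT15 on chromosome 12 (488705 to 490705), next to the rDNA, followed by 0.71 ± 0.61 at TES1 and REC107 on chromosome 10. The most negative were -1.03 ± 0.42 at TOR2 on chromosome 11 (60638 to 62638) and -0.95 ± 0.50 at RIM8, RNA15 and DST1 on chromosome 7.

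Glycolytic genes, among the most strongly transcribed in yeast, had the largest list difference. Their median log2(S/G1) went from -0.28 at 10 min to -1.09, -1.93 and -1.39 under the hpr1Δ label, and was -0.63, -0.64, -0.75 and -0.29 under the WT label. The differences were 0.44, -0.24, -0.89 and -1.05, lower for 11 of 11 measured genes at 20 and 25 min, at percentiles of 0.125 and 0. The mean over time points was -0.51 at a percentile of 0.09, and -0.29 without the 25 min arrays and -0.31 without the 20 min arrays. ENO1 (enolase) had -0.93 ± 0.68 and PGK1 (phosphoglycerate kinase) -0.84 ± 0.65, while TPI1 (triose phosphate isomerase) had -0.17 ± 0.42 and TDH3 (glyceraldehyde-3-phosphate dehydrogenase) 0.13 ± 0.86.

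**Figure D4:**
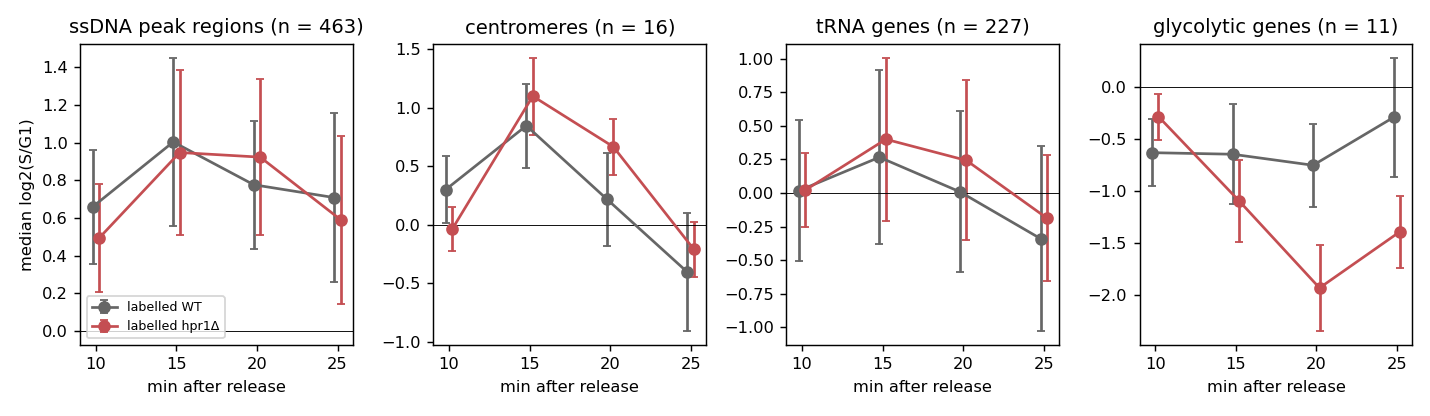
Median log2(S/G1) (y axis) at each time after release (x axis, min) for 4 sets of sites, grey for the WT label and red for the hpr1Δ label, with bars for the SD over members. Glycolytic genes reached -1.93 at 20 min under the hpr1Δ label and -0.75 under the WT label.

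tRNA gene windows were higher under the hpr1Δ label at 15 and 20 min, by 0.18 and 0.25, both at a percentile of 100. The differences at 10 and 25 min, 0.04 and 0.21, did not stand apart (percentiles of 83.2 and 81.7). Of 227 windows 155 were higher in the mean over time points, whose median was 0.17 at a percentile of 99.985. With only probes well above background it was 0.07, at a percentile of 94.7. The highest members, YNCC0008W and YNCC0009C (1.92 ± 0.37), share a window in the chromosome 3 region with the lost probes, so their ratio rests on signal near the floor. The lowest were CDC65 (-0.78 ± 0.53) and YNCG0038C (-0.67 ± 0.43). snoRNA windows differed by 0.10, at a percentile of 65.3, with SNR79 (0.80 ± 0.54) and SNR46 (0.79 ± 0.47) highest and SNR36 (-0.42 ± 0.53) and SNR45 (-0.36 ± 0.30) lowest.

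Coding regions over 3 kb had a mean difference of -0.02 at a percentile of 0.655. It was -0.0068 without 10 min, 0.0045 without 15 min, 0.0079 without 20 min and 0.028 with the deposited table, and with unmatched sets it did not stand apart, so its sign is not settled. Among these 463 genes 220 were higher, ENA5 (1.19 ± 0.83) and SWI4 (1.00 ± 0.50) most, and AMS1 (-1.05 ± 0.25) and NAB6 (-1.03 ± 0.62) were lowest. The remaining lists did not stand apart in their mean over time points, though chromosome ends, snoRNA and ribosomal protein genes did at single times. Over all 14 sets, 18 of 56 percentiles at single times and 6 of 14 of the means lay outside the central 95%. Of simulated sets of 16 windows with no planted difference, on arrays that differed only by probe noise, 8% stood apart. Other list sizes were not simulated. Ribosomal protein genes had a median of 0.01, from RPL26B (1.62 ± 1.58) and RPL7B (0.86 ± 0.47) to RPL12B (-1.03 ± 0.66) and RPS8B (-0.82 ± 0.32). Heat shock genes had -0.01, with the chaperone genes HSP78 (0.97 ± 0.41) and SSA4 (0.71 ± 0.29) highest and SSA2 (-0.77 ± 0.75) and HSP12 (-0.65 ± 0.78) lowest. Pheromone-induced genes had -0.09, from PRM2 (0.45 ± 0.69) and PRM1 (0.45 ± 0.19) to FIG1 (-0.81 ± 0.18) and KAR4 (-0.59 ± 0.53). The 5 measured histone genes had -0.23, with HTA1 at -0.82 ± 0.31, HTA2 at -0.60 ± 0.61, HTB2 at -0.14 ± 0.37 and HHT2 at -0.12 ± 0.44. Chromosome ends had 0.11, highest at the right ends of chromosomes 1 (0.92 ± 0.08) and 8 (0.56 ± 0.19) and lowest at the right end of chromosome 2 (-0.19 ± 0.20) and the left end of chromosome 13 (-0.10 ± 0.13). The 4 usable rDNA probes had -0.11, with means of 0.75, -0.07, -0.15 and -0.58.

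Across 1-kb bins, which are not replicates, the labels correlated with r of 0.52, 0.80, 0.62 and 0.34 at 10, 15, 20 and 25 min. The SD of the bin differences was 0.48, 0.44, 0.62 and 0.81, and probe noise alone would give 0.42, 0.40, 0.45 and 0.66. Across the peak regions, the WT array that correlated best with the hpr1Δ array was at 25 min for 10 min, at 15 min for 15 and 20 min, and at 25 min for 25 min, with r of 0.23, 0.77, 0.13 and 0.12. Across 1-kb bins the best WT arrays were instead at 10, 15, 15 and 20 min, with r of 0.52, 0.80, 0.65 and 0.36.

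In all, 1214 bins were higher by at least 0.5 with the same sign at all 4 time points on the arrays labelled hpr1Δ, and 786 were lower. Probe noise alone gave a mean of 145.7 and 144.4 such bins over 100 simulations. Such noise holds no effect shared by the 4 arrays of a slide, which could keep its sign at all 4 time points. Counts above those of noise therefore cannot be told apart from an effect of the slide. The excess of higher bins was not kept with only probes well above background, which gave 374 higher and 457 lower, or with normexp, which gave 530 and 748. The bins of the rule that were higher overlapped VBA3 (chromosome 3, 9001 to 10000, 1.98 ± 0.54), PRP6 on chromosome 2 (1.86 ± 0.97), LPX2 on chromosome 11 (1.80 ± 0.94), VPS64 (1.64 ± 0.42) and PDR15 (1.61 ± 0.77) on chromosome 4, and in 5 cases no annotated gene. Among the latter, the bin at 149001 on chromosome 3 (1.98 ± 0.92) holds lost probes. The bins that were lower overlapped AXL1 (chromosome 16, 783001 to 784000, -1.57 ± 0.68), GSY2 on chromosome 12 (-1.56 ± 0.50), ROX1 (-1.54 ± 1.19), CDC20 on chromosome 7 (-1.45 ± 0.62), FRK1 (-1.44 ± 0.89), RGI1 (-1.40 ± 0.49), TCB1 (-1.38 ± 0.19), TRM12 (-1.34 ± 0.54), MUK1 and BTS1 (-1.32 ± 0.81), and BDH1 and ECM1 (-1.32 ± 0.74). Each bin rested on 2 to 4 probes. In the 10 higher bins the G1 signal under the WT label was -2.35 to -1.19 log2 units from the array median, so these ratios came from dim probes.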

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

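Only the test of compressed ratios was written down before its result was seen, and a condition was added to its written rule. All other tests in this part were chosen after the results. No group held enough arrays for a test of outlying arrays.

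Signal in single channels, which no S/G1 comparison covered, went against the strain labels: RGP1 had a mean Cy5 signal of -5.86 log2 units on the arrays labelled hpr1Δ, where HPR1 was at -0.11, and the BY4741 marker genes had a mean Cy3 signal of -0.37 on the arrays labelled WT. A shift of the probe annotation would need gene positions near HPR1 to be off by about a gene's length, and the median distance to the reference positions was 6.5 bp over 12 genes. A slide too dim to show a loss would leave the lost chromosome 3 runs and the markers alike. On the arrays labelled WT the runs, which are other probes, lay -4.32 log2 units from the markers in Cy3 but only -1.45 in Cy5. The markers thus lay above the lowest Cy3 signal of that slide. A low probe there need not mark lost sequence, however. A YCF1 probe (726076 to 726135) read -4.69 to -4.13 there and -0.32 to 0.27 under the hpr1Δ label, although YCF1 as a whole lay at -0.68 there. The Cy3 gap therefore does not show that a loss would be visible, and a slide too dim stays open in both channels. With HPR1 at -0.11 under the hpr1Δ label, the values are consistent with strains other than those named: a BY4741-type strain lacking RGP1 and a strain that carries the marker genes, and the arrays cannot say at which step this arose.

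The strain difference at centromeres had opposite signs at 2 time points, -0.41 at 10 min and 0.29 at 15 min, each with a single array per label, and the change between times was not tested. At 10 min the region 3 to 10 kb away was lower too (-0.32, 16 of 16 sites) and the local difference was -0.06, so the 10 min value was not particular to the windows. At 15 min a shift of the whole region stays open: the region 3 to 10 kb away differed by 0.094, and the local difference was 0.18 (percentile 97.0), which stood apart with loess (0.29), robust SD scaling (0.20), the deposited table or flagged spots kept (0.19 each) and without any of 8 centromeres (0.22), but not with normexp (0.034) or only probes well above background (0.055). Dim probes stay open: at the 11 centromeres with enough bright probes the 15 min difference was -0.0018 with those probes and 0.12 with all probes (SD 0.39 in both). The slide also stays open, since 0 slides held both labels, and a difference between the strains was not tested.

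Glycolytic genes were lower on the arrays labelled hpr1Δ in the mean over time points, with a median over genes of -0.51. At 10 min they were higher, by 0.44. Dim probes alone are argued against, because the value was -0.46 with only probes well above background. Compressed ratios on the dim slide stay open: among gene sets matched on their level under the hpr1Δ label the list lay at a percentile of 10.8, but that level is part of the difference, so the test decides nothing. With arrays scaled to a common robust SD the list was at -0.69 (percentile 1.28). The robust SD was 0.75 to 1.15 under the WT label and 0.39 to 0.86 under the hpr1Δ label. Scaling therefore does not undo a compression of the WT ratios, and that value decides nothing about it. At 10 min the list was further from 0 under the WT label (-0.63) than under the hpr1Δ label (-0.28). The slide stays open here too, with 0 slides shared, and a difference in transcription between the strains was not tested.

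Mitochondrial probes, outside every comparison, gave a mean Cy5 signal of 2.93 ± 0.28 log2 units (SD, 4 arrays) above the nuclear median on the arrays labelled WT and 5.72 ± 0.28 on those labelled hpr1Δ. The nuclear Cy5 median on the slide labelled WT was only 3.61 to 16.6, and 11.4 to 31.4% of its nuclear Cy5 values were surrogates. Slide and label cannot be told apart here either.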

How the results depend on the processing

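The local centromere comparison, peaks called under a single label, random sets matched on the distance to peaks and the RGP1 reading were added after the results were seen. Matching on the distance to annotated origins was not run and was replaced by the distance to ssDNA peak regions. No paired test was run, because no replicates pair the labels. Differences were taken between arrays of the same time point. A model of strain label with time as a block would use time points as replicates and was not run. Set results not named under a setting kept their place inside or outside the central 95% of random sets, and those outside kept their direction. The causes of these changes were not tested.

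With normexp background correction, the centromere difference changed sign at 25 min (-0.25, percentile 0.01), and newly stood apart at 20 min (0.18, percentile 99.3). The local centromere difference no longer stood apart in the mean (0.019, percentile 90.2). The difference at peak regions changed sign at 25 min (0.59, percentile 98.4) and in the mean (0.36, percentile 100), and newly stood apart at 10 min (-0.13, percentile 99.5), at 15 min (0.58, percentile 100) and at 20 min (0.38, percentile 100). List differences changed sign for pericentromeres (0.085, percentile 47.8), and newly stood apart for heat shock genes (-0.39, percentile 0.47) and for pheromone-induced genes (-0.48, percentile 1.3), and moved for chromosome ends (-0.13, percentile 80.4) and for histone genes (0.092, percentile 64). The centromere level on the WT 10 min array no longer stood apart at 0.12 (percentile 61), on the hpr1Δ 10 min array newly stood apart at -0.25 (percentile 0.58) and on the hpr1Δ 25 min array newly stood apart at -0.18 (percentile 0.31). Raised bins numbered 793 at WT 15 min, 683 at WT 20 min, 532 at WT 25 min and 1553 at hpr1Δ 20 min. The bins higher under the hpr1Δ label numbered 530. The r between labels was 0.61 at 10 min, 0.65 at 15 min, 0.45 at 20 min and 0.49 at 25 min.

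With loess within each array, the local difference at centromeres newly stood apart at 15 min (0.29, percentile 99.7) and at 25 min (0.36, percentile 99.5). The peak region difference changed sign at 15 min (-0.17, percentile 0), and newly stood apart at 20 min (0.070, percentile 0.71). Among the lists, the difference newly stood apart for snoRNA genes (0.17, percentile 99.99), for chromosome ends (0.13, percentile 99.98), for heat shock genes (-0.37, percentile 2.21), for pheromone-induced genes (-0.34, percentile 1.83) and for histone genes (-0.63, percentile 0.18). The level at centromeres on the WT 20 min array newly stood apart at 0.36 (percentile 99.1) and on the hpr1Δ 25 min array moved to 0.025 (percentile 66.5). Raised bins numbered 932 at WT 25 min and 1161 at hpr1Δ 25 min. The bins higher under the hpr1Δ label numbered 735. The r between labels was 0.76 at 15 min. With all arrays scaled to a common robust SD, the local centromere difference no longer stood apart in the mean (0.17, percentile 95.2), and newly stood apart at 15 min (0.20, percentile 98.3). Peak regions changed sign at 25 min (0.29, percentile 11.3) and in the mean (0.24, percentile 1.76), and newly stood apart at 15 min (0.31, percentile 0.95) and at 20 min (0.14, percentile 0.205), and moved at 10 min (0.31, percentile 92.5). List differences newly stood apart for histone genes (-0.44, percentile 0.77). Raised bins numbered 1234 at WT 25 min and 2486 at hpr1Δ 10 min.

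With the deposited ratio table, not centred, the local difference at centromeres newly stood apart at 15 min (0.19, percentile 97.9). The difference at peak regions changed sign at 25 min (0.12, percentile 0.16) and in the mean (0.017, percentile 0.49). Among the lists, the difference changed sign for coding regions over 3 kb (0.028, percentile 0.35). With only probes well above background on all 8 arrays, the centromere difference changed sign at 15 min (-0.0018, percentile 48.7). The local centromere difference changed sign in the mean (-0.019, percentile 47.2), and no longer stood apart at 20 min (0.19, percentile 90.7). The peak region difference changed sign at 25 min (0.052, percentile 29.7) and in the mean (0.030, percentile 47.4), and newly stood apart at 10 min (-0.093, percentile 98.8). List differences no longer stood apart for tRNA genes (0.069, percentile 94.7). The centromere level on the WT 20 min array newly stood apart at 0.43 (percentile 98.5). Raised bins numbered 1069 at WT 10 min, 1756 at WT 15 min, 1300 at WT 20 min, 1189 at WT 25 min, 1528 at hpr1Δ 15 min, 1648 at hpr1Δ 20 min and 1171 at hpr1Δ 25 min. The bins higher under the hpr1Δ label numbered 374 and those lower under the hpr1Δ label numbered 457. The r between labels was 0.63 at 10 min, 0.86 at 15 min, 0.73 at 20 min and 0.46 at 25 min. With outlier-flagged spots kept, the local difference at centromeres newly stood apart at 15 min (0.19, percentile 97.9).

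With probes within 0.5 kb, peak regions changed sign at 25 min (0.051, percentile 98.9), and no longer stood apart in the mean (-0.0041, percentile 78). The level at centromeres on the WT 20 min array newly stood apart at 0.48 (percentile 99.1). With probes within 2.5 kb, the centromere difference no longer stood apart at 15 min (0.16, percentile 97.4). The difference at peak regions changed sign at 25 min (0.10, percentile 71.2) and in the mean (0.027, percentile 63.6), and newly stood apart at 10 min (-0.12, percentile 98.7). The centromere level on the WT 20 min array newly stood apart at 0.41 (percentile 99.8). With probes within 5 kb, the peak region difference changed sign at 25 min (0.091, percentile 28.5), and no longer stood apart in the mean (-0.0079, percentile 10.3). The level at centromeres on the WT 20 min array newly stood apart at 0.46 (percentile 99.98) and the peak region level on the WT 25 min array changed sign at -0.0018 (percentile 100). With means over sites, the centromere level on the WT 20 min array newly stood apart at 0.28 (percentile 98.9). With random sets not matched, peak regions newly stood apart at 10 min (-0.14, percentile 0) and at 20 min (0.17, percentile 100). Among the lists, the difference no longer stood apart for coding regions over 3 kb (-0.023, percentile 2.6).

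With a bin threshold of 0.3, raised bins numbered 3035 at WT 10 min, 2077 at hpr1Δ 10 min and 3221 at hpr1Δ 25 min. The bins higher under the hpr1Δ label numbered 1842 and those lower under the hpr1Δ label numbered 1265. With a bin threshold of 1, raised bins numbered 321 at WT 10 min, 1080 at WT 15 min, 531 at WT 20 min, 554 at WT 25 min, 68 at hpr1Δ 10 min, 1039 at hpr1Δ 15 min, 900 at hpr1Δ 20 min and 320 at hpr1Δ 25 min. The bins higher under the hpr1Δ label numbered 208 and those lower under the hpr1Δ label numbered 74. With 5-kb bins, the r between labels was 0.88 at 15 min and 0.72 at 20 min. With peaks called on the arrays labelled WT, the difference at peak regions changed sign at 15 min (-0.085, percentile 0) and at 20 min (-0.12, percentile 0), and newly stood apart at 10 min (-0.33, percentile 0). With peaks called on the arrays labelled hpr1Δ, the peak region difference changed sign at 10 min (0.088, percentile 100), at 25 min (0.34, percentile 100) and in the mean (0.26, percentile 100), and newly stood apart at 15 min (0.15, percentile 100) and at 20 min (0.47, percentile 100). Before dye normalization, the RGP1 signal moved to -4.54 (Cy3, hpr1Δ 10 min), -4.86 (Cy3, hpr1Δ 15 min), -4.54 (Cy5, hpr1Δ 10 min) and -4.05 (Cy5, hpr1Δ 15 min).

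Leaving out a time point or a centromere moved the mean centromere difference between 0.0066 and 0.23. The centromere differences ranged from -0.44 to -0.39 at 10 min, 0.25 to 0.33 at 15 min, 0.094 to 0.20 at 20 min and 0.076 to 0.11 at 25 min when each centromere was left out. The local centromere difference ranged from -0.071 to -0.045, 0.13 to 0.22, 0.32 to 0.38 and 0.22 to 0.30 at the 4 time points and from 0.091 to 0.30 in the mean. At 15 min it newly stood apart, at 0.22, without CEN3, CEN4, CEN5, CEN6, CEN10, CEN14, CEN15 or CEN16. Its mean no longer stood apart without 15 min (0.18), 20 min (0.091), CEN2, CEN7 or CEN11 (0.20 each).

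Leaving out time points, the mean peak region difference ranged from -0.096 to 0.015; it changed sign without 10 min (0.015) and no longer stood apart without 25 min (-0.015). Chromosome ends ranged from 0.075 to 0.23 and newly stood apart without 20 min (0.23) or 25 min (0.12). Long coding regions ranged from -0.086 to 0.0079, no longer stood apart without 10 min (-0.0068) and changed sign without 15 min (0.0045) or 20 min (0.0079). Pericentromeres ranged from -0.23 to -0.059 and no longer stood apart without 10 min (-0.059). The ranges were -0.74 to -0.29 for glycolytic genes, -0.11 to 0.13 for heat shock genes, -0.31 to -0.16 for histone genes, -0.13 to 0.0071 for pheromone-induced genes, -0.20 to -0.012 for rDNA probes, -0.0015 to 0.027 for ribosomal protein genes, 0.10 to 0.14 for snoRNA genes and 0.14 to 0.24 for tRNA genes. The bins higher under the hpr1Δ label ranged from 1030 to 1693 and the lower ones from 763 to 1213, the last without 15 min.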

Other observations

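Mitochondrial DNA, which lay outside every comparison above, gave more G1 (Cy5) than S-phase (Cy3) signal relative to nuclear DNA on all 8 arrays. Its log2(S/G1) lay at -2.46 ± 0.35 (SD, 4 arrays) from the nuclear median under the WT label and at -2.02 ± 0.69 under the hpr1Δ label. With no dye swap, phase and dye cannot be told apart here.

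The log2(S/G1) of chromosome ends was low at 20 and 25 min under both labels and at 15 min under the WT label. A low ratio can come from either channel, and the channels were not read alone here. Under the hpr1Δ label chromosome ends had been above random segments at 10 min (0.08, percentile 99.8) and did not stand apart at 15 min (-0.20, percentile 5.6). Under the WT label they did not stand apart at 10 min (-0.16, percentile 3.63) and stood below random segments at 15 min (-0.42, percentile 0.03). Their median log2(S/G1) was -0.46 and -0.47 at 20 and 25 min under the WT label and -0.62 and -0.31 under the hpr1Δ label, each at a percentile of 0 among random 30-kb segments. Coding regions over 3 kb and ribosomal protein genes were also below random gene sets on all 8 arrays, with medians of -0.13 to -0.35 and of -0.28 to -0.58. So were pheromone-induced genes, with medians of -0.53 to -0.98. Glycolytic genes were below random sets except at WT 25 min, and heat shock genes except at WT 25 min and hpr1Δ 10 min. A low ratio was thus not particular to long or ribosomal protein genes. At 25 min tRNA gene windows, which had been at 0.27 and 0.40 at 15 min, were at -0.34 under the WT label and -0.19 under the hpr1Δ label.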
